A study of Homo sapiens with 8 samples.

How the data were processed

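RNA was measured in H1 cells, an established human embryonic stem cell line, with an Msx1-tdTomato reporter. Per the labels' protocols, the cells received Activin A at 50 ng/mL, the GSK3 inhibitor CHIR99021 at 6 µM, BMP4 at 40 ng/mL and FGF2 at 10 ng/mL on day 0, and BMP4 at 60 ng/mL with CHIR99021 at 1 µM for 3 days from day 1. They were dissociated on day 4, pelleted at 25000 cells per well with FGF8 and FGF10 at 500 ng/mL each or with Mock treatment, moved on day 5, cultured for 3 days and sorted on day 8. The labels give all libraries one protocol text, which describes the FGF8+10 medium, so the composition of the Mock medium is not known here. RNA was extracted with TRI Reagent and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The 8 libraries fall into 4 groups of 2 by treatment and sorted population, as the sample titles state.

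The authors deposited 1 table of raw counts per gene name, with 61209 gene names. Per the submitters' processing notes, reads were checked with FastQC 0.11.8 and aligned with HISAT2 2.1.0 to GRCh38. Per the file headers, counting was done with featureCounts 2.0.3, which assigns aligned reads to annotated exons, by gene name on GENCODE release 42. The recorded command has the paired-end option but not the option that counts pairs, so both mates of a pair were counted and the counts overstate the number of independent fragments. It sets no strand, so a gene and an overlapping antisense gene cannot be told apart, and reads that overlap more than 1 gene or map to several places were dropped, which lowers genes with near-identical copies. Trimming and filters before alignment are not given in the sources used here. The table has 0 blank or summary lines and 0 sample columns that were not used.

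Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and with DESeq2 1.42.0 as an alternative. Of 39416 genes with any count, 22554 passed filterByExpr with the 4 groups, and at least 99.96% of each library's counts lay in them. Of the tested names, 17.3% were Ensembl identifiers without a symbol. Libraries were scaled by TMM, with factors of 1.055 to 1.065 under FGF8+10 and 0.936 to 0.952 under Mock. One quasi-likelihood model (robust) was fitted over all 8 libraries with a mean per group, which leaves 4 residual degrees of freedom, and 5 two-sided contrasts were tested. Those were FGF8+10 against Mock in each population, Pdgfra-positive against Pdgfra-low under each treatment, and the difference between the FGF8+10 effects. Benjamini-Hochberg adjustment was made within each contrast at 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. For a gene near 0 CPM in 1 group, this can understate the spread between libraries and the counting error. CPM are counts scaled by the TMM-adjusted library size. With 2 libraries per group, no other split of the samples was tested.

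Depth ranged from 47698561 to 64390444 counts per library. The common biological coefficient of variation was 4.06% and the median over single genes 8.58%. The chi-square per gene between replicates of a group was 3.45 to 3.75, a value that counting both mates raises by itself, so it does not measure the spread between libraries. The log2 CPM of replicates correlated across genes at Pearson's r of 0.9976 to 0.9984, so none was a second deposit of another. Exact binomial 95% intervals were computed for shares and for ratios of genes with 1 to 3 counts in a group, with 2 mate counts taken as 1 pair, and a group without reads was set at a floor of 6 counts, or 3 pairs, over the group. Taking pairs was chosen after the results were seen. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The fitted log2 fold change of a gene with so few reads depends on the prior count.

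A total of 31 gene lists were fixed before the data were examined. They are sort genes (MSX1 and PDGFRA), limb mesenchyme, lateral plate mesoderm, FGF and ERK targets, anterior and central HOX, posterior HOX, cartilage, fibrous connective tissue matrix, BMP targets and antagonists, WNT targets, hedgehog targets, retinoic acid pathway, cell cycle, hypoxia response, amino acid stress response, p53 targets, dissociation and heat shock response, cholesterol synthesis, mitochondrial transcripts and replication histones. The others hold markers of cell types the gates could hold, namely endothelial, cardiac muscle, smooth muscle, skeletal muscle and somite, pluripotency, neural and neural crest, epithelial and surface ectoderm, endoderm, blood, mesothelium and epicardium, and kidney lineage markers. Lists with at least 3 tested members (29) were tested with camera on voom values, with the preset inter-gene correlation of 0.01, and adjusted over the lists of a contrast. Camera compares a list with all other genes. Camera with an estimated correlation, and fry, which tests whether a list's genes move one way on balance, stood beside it. Of 65 calls over the 5 contrasts, 40 also passed with an estimated correlation. Where the estimate lay below the preset 0.01, a larger p does not come from a stronger correlation between a list's genes. The signs of the median, the mean and the test differed in 22 of 145 list tests, of which 1 was a call.

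Genes were named by a rule fixed before the data were examined. For each FGF8+10 contrast it took the 10 higher and 10 lower genes with the largest log2 fold change, and for the other contrasts 6 and 6, among genes past the threshold with at least 5 CPM in the higher group, replicates that did not overlap and a gene symbol, leaving out XIST and genes on the Y chromosome. Replicates that did not overlap were not asked for in the difference between the FGF8+10 effects. MSX1, PDGFRA, FGF8, FGF10 and the 4 FGF receptors could always be named, and up to 4 members of each list with the smallest adjusted p. Some single genes that the rule allows are not reported here. Coordinates are those of the deposited table.

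The edgeR gene test and the camera list test, but not the other steps, were run on simulated counts. For FGF8+10 against Mock in Pdgfra-positive cells, with 50 genes changed at each fold among 21782, 56% were recovered at 1.2-fold, 78% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 7 false calls. In the simulation of the list test, the shifted list was called, and so was 1 of the lists that were not shifted. Both simulations gave the groups 1 mean per gene apart from few changed genes. In the data 50.9% of genes passed the threshold in that comparison, so the simulated rates do not carry over to it. Alternatives were other scalings (median-ratio factors, library totals), other filters (none, or at least 5 CPM in 2 libraries), DESeq2, limma-voom, a fit of the compared groups alone, the replicate number as a block, leaving out each library in turn and, chosen after seeing the data, halved counts and a test against a 2-fold change (glmTreat).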

Results

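Gene expression was measured by RNA sequencing in H1 human embryonic stem cells, an established line, that carried a fluorescent Msx1-tdTomato reporter and had been differentiated towards lateral plate mesoderm. At day 4 the cells were dissociated and pelleted at 25000 cells per well, and the pellets received FGF8 and FGF10, ligands of the FGF receptors, at 500 ng/mL each (FGF8+10) or a Mock treatment whose medium the labels do not describe. At day 8 Msx1-positive cells were sorted into Pdgfra-positive and Pdgfra-low populations. This gave 4 groups of 2 libraries each, 8 libraries in all. The libraries held 63912334 and 64390444 counts for FGF8+10 Pdgfra-positive, 49790227 and 55329666 for FGF8+10 Pdgfra-low, 47698561 and 51398575 for Mock Pdgfra-positive, and 63990830 and 63700869 for Mock Pdgfra-low cells. Both mates of a read pair were counted, so a count of 0 was bounded at 6 counts, or 3 pairs. At these depths 6 counts correspond to between 0.0932 and 0.126 CPM (counts scaled to library size) in 1 library. A total of 22554 genes entered the tests. Values below are TMM-scaled CPM as mean ± SD (n = 2 libraries) or log2 fold changes ± SE from the model over all 8 libraries, with 2 libraries per group. Coordinates are GRCh38.

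The sort genes checked the labels. PDGFRA, the receptor used for the gate (chromosome 4, 54229280 to 54298245), stood at 714 ± 2.9 CPM in Pdgfra-positive and 286 ± 9.3 CPM in Pdgfra-low cells under FGF8+10, and at 454 ± 1.9 and 192 ± 3.6 CPM under Mock. Since the gate selected on it, its difference between the populations is not a finding. MSX1 (chromosome 4, 4859665 to 4863936), a homeobox gene of limb mesenchyme whose reporter was the first gate, stood at 50.3 ± 1.7 and 50.7 ± 3.0 CPM with FGF8+10 and at 21.7 ± 0.57 and 26.2 ± 0.024 CPM with Mock in Pdgfra-positive and Pdgfra-low cells. The cells were sorted after the treatment, and both sort genes were higher with FGF8+10. A gate may therefore hold different cells under FGF8+10 and under Mock. Differences between treatments cannot tell a response of the same cells from a change in which cells the gate took. On the first principal component of log2 CPM, with 65.7% of the variance, every FGF8+10 library lay between -92.65 and -77.29 and every Mock library between 75.8 and 93.81, and the second, with 12.8%, separated the populations. COL3A1, the most abundant fibrillar collagen transcript measured here, took 2.50% and 2.52% of all counts in the FGF8+10 Pdgfra-positive libraries and 5.69% and 5.67% in the Mock Pdgfra-positive libraries. The exact binomial 95% intervals, with 2 counts taken as 1 pair, were at most 0.0186 percentage points wide and covered counting error only.

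**Figure D1:**
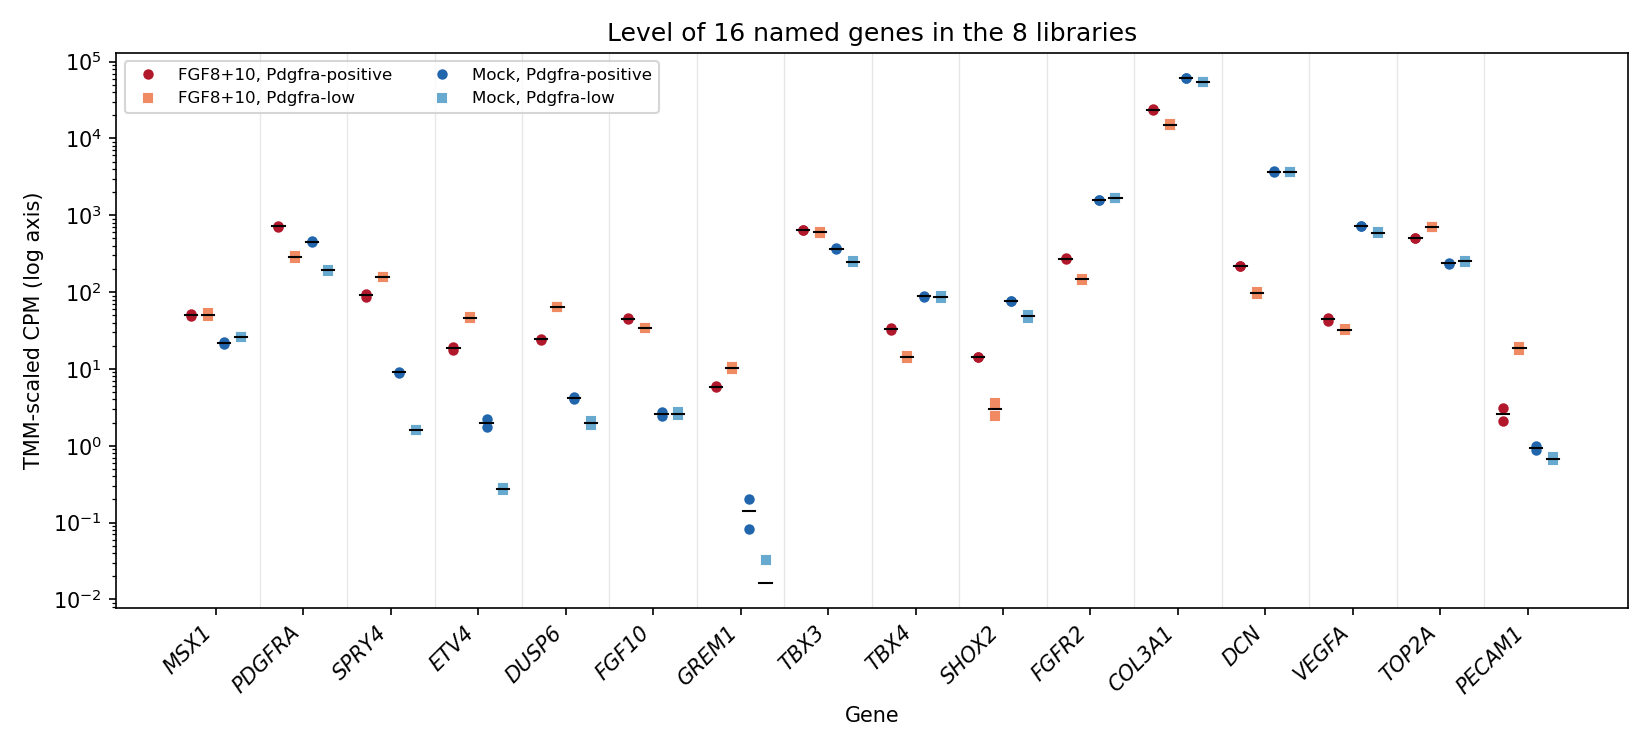
TMM-scaled CPM (log axis) of 16 named genes in each of the 8 libraries, with 2 points per group and a bar at the group mean. FGF10, SPRY4, ETV4 and DUSP6 lay higher in every FGF8+10 library than in any Mock library, and DCN, VEGFA, FGFR2 and COL3A1 lay lower. GREM1 had no read in 1 Mock Pdgfra-low library, which therefore has no point.

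The first comparison asked what FGF8+10, which the series title credits with maturing lateral-plate-like cells to limb-mesenchyme-like ones, changed in the Pdgfra-positive cells. With FGF8+10, FGF10 itself, the limb bud mesenchyme ligand (chromosome 5, 44300247 to 44389706), rose from 2.59 ± 0.18 to 45.1 ± 1.1 CPM (log2 fold change 4.12 ± 0.096, adjusted p = 7.59e-35). The ERK feedback inhibitors SPRY1 and SPRY4 rose by 3.57 ± 0.043 and 3.33 ± 0.057 on the log2 scale, and MSX1 by 1.21 ± 0.060. Among the receptors, FGFR1 rose (log2 fold change 1.01 ± 0.030) while FGFR2, FGFR3 and FGFR4 fell (log2 fold changes -2.55 ± 0.021, -3.25 ± 0.051 and -1.35 ± 0.27). DCN, which encodes the proteoglycan decorin, fell from 3685 ± 51 to 216 ± 0.58 CPM, and VEGFA, an endothelial growth factor gene, from 727 ± 10 to 44.1 ± 2.5 CPM.

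The 10 genes with the largest rises were DCX, GREM1, HLX, LGR5, TM4SF1, TNC, FGF9, TGFBI, KCNA3 and MARCHF4, with log2 fold changes from 4.67 to 5.66. GREM1, a secreted BMP antagonist of the limb bud (chromosome 15, 32718004 to 32745106), rose by 5.37 ± 0.29, the stem cell receptor LGR5 by 5.26 ± 0.19, and the matrix protein genes TNC and TGFBI by 4.88 ± 0.044 and 4.79 ± 0.029. TGFBI reached 894 ± 6.4 CPM from 32.3 ± 0.23 CPM. The 10 with the largest falls were SLC18A3, RPSAP44, ATP12A, SMOC2, DMRT2, ALOX5, ZNF385B, THBD, NPY and SUCNR1. SMOC2, a secreted matricellular protein gene, went from 105 ± 0.53 to 0.185 ± 0.095 CPM (log2 fold change -9.14 ± 0.12). Its FGF8+10 libraries differed by more than this SE implies, with an SD of 0.095 around a mean of 0.185. NPY, which encodes neuropeptide Y, went from 231 ± 0.15 to 0.989 ± 0.088 CPM, and THBD (thrombomodulin) from 34.3 ± 1.5 to 0.125 ± 0.0099 CPM. SLC18A3, the vesicular acetylcholine transporter, had no read in the FGF8+10 Pdgfra-positive libraries and 13.3 CPM with Mock, so that it was at least 300-fold lower against a floor of 6 counts over the group. On the same basis ATP12A, a proton pump gene, was at least 142-fold lower and RPSAP44 at least 207-fold lower. RPSAP44 is a pseudogene of RPSA, so reads shared with its parent gene leave its value uncertain. DMRT2 had 2 counts in the FGF8+10 Pdgfra-positive group, which may be 1 pair, so its ratio of 409 has an exact binomial 95% interval of 72.7 to 16200 over pairs.

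Of 25 FGF and ERK targets, 16 were higher and 6 lower (16 and 6 adjusted over the list alone), with camera adjusted p = 0.000155, and adjusted p = 0.0343 with an estimated correlation. The 6 that fell included the receptor genes FGFR2 and FGFR3, while the receptor gene FGFR1 was among the 16 that rose. Of 25 cell cycle genes, 24 were higher and 0 lower (24 and 0 adjusted over the list alone), with camera adjusted p = 1.16e-17, and adjusted p = 0.0166 with an estimated correlation. TOP2A rose by 1.12 ± 0.023, CENPF by 1.24 ± 0.030 and BUB1 by 1.49 ± 0.046. Of 13 BMP targets and antagonists, 11 were higher and 1 lower (12 and 1 adjusted over the list alone), with camera adjusted p = 1.87e-06, and adjusted p = 0.031 with an estimated correlation. Among these were the BMP pseudoreceptor gene BAMBI (1.34 ± 0.022) and SMAD9 (1.96 ± 0.046).

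Among HOX genes, which pattern the body and limb axes, of 21 anterior and central HOX genes, 16 were higher and 0 lower (16 and 0 adjusted over the list alone), with camera adjusted p = 6.79e-05, and adjusted p = 0.034 with an estimated correlation. HOXB8 rose by 1.75 ± 0.080 and HOXB3 by 1.35 ± 0.043. Of 14 posterior HOX genes, 10 were higher and 3 lower (10 and 3 adjusted over the list alone), with camera adjusted p = 0.0188, but adjusted p = 0.114 with an estimated correlation. HOXD9, HOXD10 and HOXD11 rose by 1.52 ± 0.071, 1.30 ± 0.052 and 1.42 ± 0.11, and HOXA13, the most distal limb HOX gene of its cluster, fell (log2 fold change -0.99 ± 0.036). HOXD10 and HOXD11 share annotated exon sequence, as do HOXB3 and an antisense transcript. The counts are unstranded and reads over more than 1 gene were dropped, so these genes were counted on part of their exons. Neighbours within a cluster may still not be fully separate measurements.

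**Figure D2:**
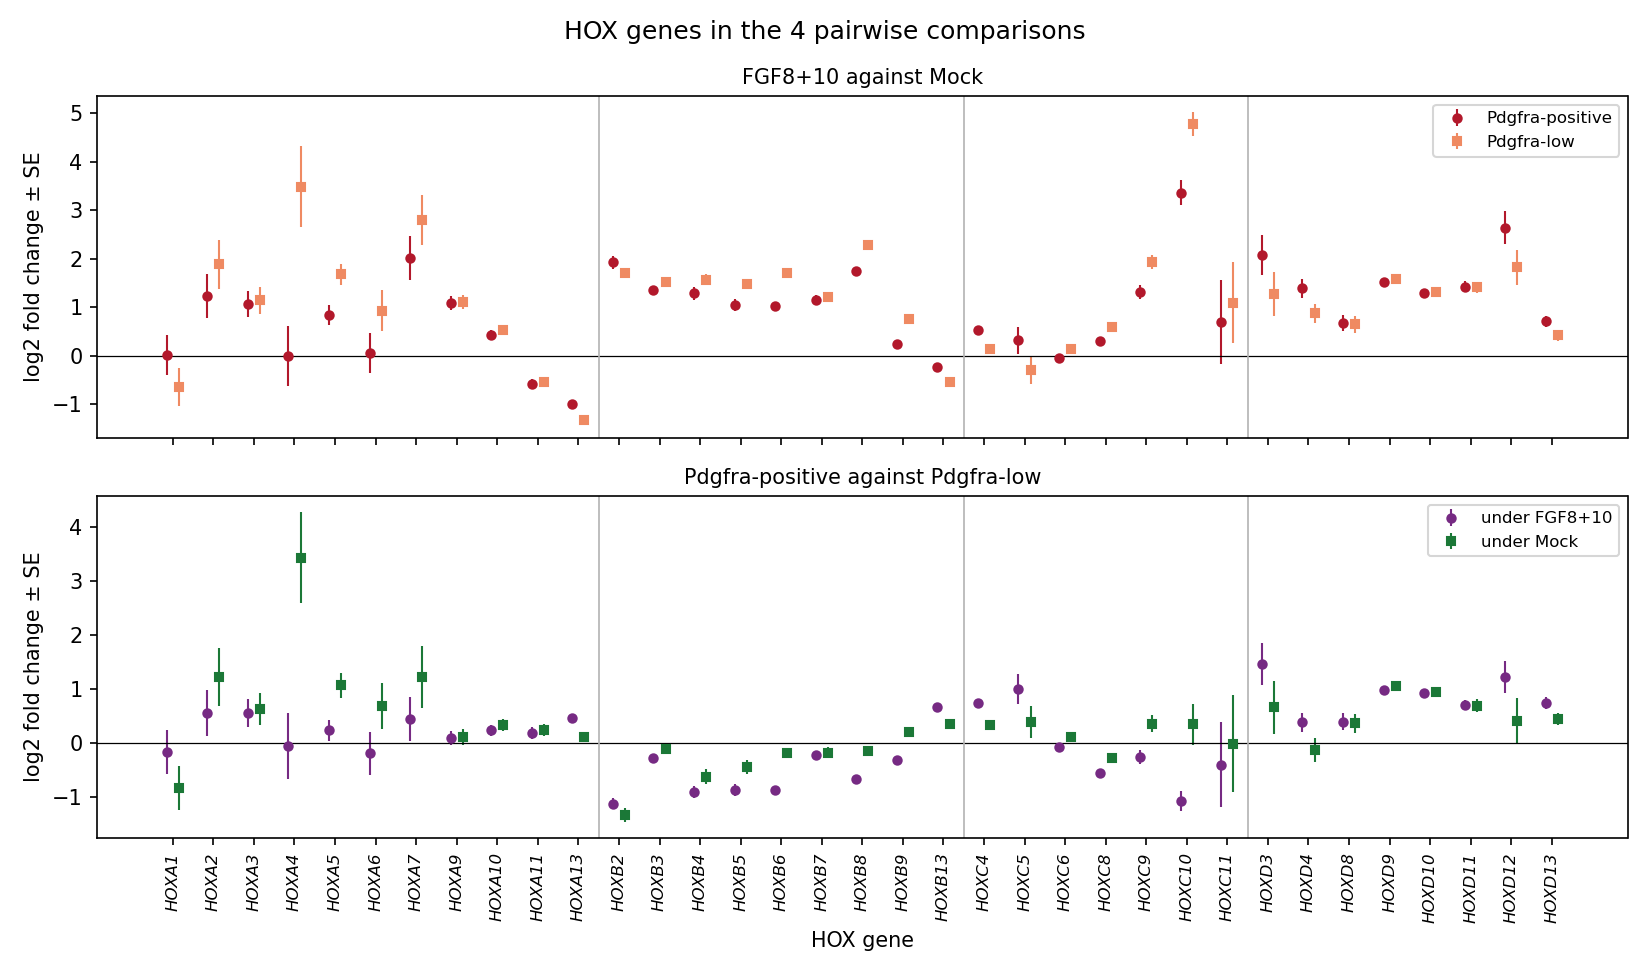
log2 fold change ± SE of each tested HOX gene (x axis, by cluster) for FGF8+10 against Mock in both populations (upper panel) and for Pdgfra-positive against Pdgfra-low under both treatments (lower panel). HOXB2 to HOXB8 and HOXD9 to HOXD12 lie above 0 in both series of the upper panel, and HOXA11, HOXA13 and HOXB13 lie below. HOXD9 to HOXD11 lie above 0 in the lower panel and HOXB2 below.

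Other lists fell. Of 20 fibrous connective tissue matrix genes, 6 were higher and 14 lower (6 and 14 adjusted over the list alone), with camera adjusted p = 1.2e-06, and adjusted p = 0.031 with an estimated correlation. COL1A2 and POSTN fell (log2 fold changes -1.86 ± 0.015 and -2.75 ± 0.023), whereas FBN1 (fibrillin-1) rose by 2.49 ± 0.017. Of 14 amino acid stress response genes, 0 were higher and 14 lower (0 and 14 adjusted over the list alone), with camera adjusted p = 2.49e-13, and adjusted p = 0.0178 with an estimated correlation. The serine and folate pathway genes PHGDH, PSAT1 and MTHFD2 had log2 fold changes of -1.23 ± 0.026, -1.60 ± 0.031 and -2.00 ± 0.038. Of 16 hypoxia response genes, 1 was higher and 11 lower (1 and 11 adjusted over the list alone), with camera adjusted p = 1.3e-05, and adjusted p = 0.031 with an estimated correlation. VEGFA had a log2 fold change of -4.04 ± 0.031 and the glucose transporter gene SLC2A1 of -2.61 ± 0.044. Of 20 dissociation and heat shock response genes, 2 were higher and 16 lower (3 and 16 adjusted over the list alone), with camera adjusted p = 1.23e-05, and adjusted p = 0.031 with an estimated correlation. Of 18 cholesterol synthesis genes, 3 were higher and 15 lower (3 and 15 adjusted over the list alone), with camera adjusted p = 5.46e-06, and adjusted p = 0.031 with an estimated correlation. KLF4, a pluripotency and stress response factor gene, had a log2 fold change of -3.61 ± 0.15 and DHCR7, a sterol reductase gene, of -1.01 ± 0.037.

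Markers of other cell types also moved. Of 10 cardiac muscle markers, 0 were higher and 8 lower (0 and 8 adjusted over the list alone), with camera adjusted p = 0.00114, but adjusted p = 0.0604 with an estimated correlation. They were led by the cardiac troponin gene TNNT2, at 62.0 ± 5.2 CPM with Mock and 0.738 ± 0.1 CPM with FGF8+10. Of 15 endothelial markers, 9 were higher and 2 lower (10 and 2 adjusted over the list alone), with camera adjusted p = 0.0178, but adjusted p = 0.114 with an estimated correlation. The angiopoietin receptor gene TEK rose by 1.63 ± 0.025 and TIE1 fell (log2 fold change -1.22 ± 0.17).

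Several lists had members that moved in both directions and did not pass camera. Of 24 limb mesenchyme genes, 8 were higher and 11 lower (8 and 11 adjusted over the list alone), with camera adjusted p = 0.602. FGF10 and TBX3 rose (4.12 ± 0.096 and 0.82 ± 0.024), while TBX2 and SHOX2 fell (log2 fold changes -2.02 ± 0.043 and -2.41 ± 0.069). Of 18 lateral plate mesoderm genes, 8 were higher and 6 lower (8 and 6 adjusted over the list alone), with camera adjusted p = 0.543. ISL1 rose by 3.09 ± 0.13, and OSR1 fell (log2 fold change -1.25 ± 0.052). Of 23 cartilage genes, 6 were higher and 10 lower (6 and 10 adjusted over the list alone), with camera adjusted p = 0.108. ACAN (aggrecan) had a log2 fold change of -4.15 ± 0.11 and COL11A1 of 1.30 ± 0.024. Of 14 WNT targets, 5 were higher and 3 lower (5 and 3 adjusted over the list alone), with camera adjusted p = 0.257. Of 9 hedgehog targets, 3 were higher and 4 lower (4 and 4 adjusted over the list alone), with camera adjusted p = 0.433. Of 11 retinoic acid pathway genes, 3 were higher and 3 lower (3 and 3 adjusted over the list alone), with camera adjusted p = 0.984. ALDH1A2, the embryonic retinoic acid synthesising enzyme, rose by 3.35 ± 0.076, and PTCH1, a hedgehog receptor and target, fell (log2 fold change -1.49 ± 0.043).

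The remaining lists did not pass camera either. Of 14 p53 targets, 6 were higher and 4 lower (6 and 5 adjusted over the list alone), with camera adjusted p = 0.334. Of 12 replication histones, 1 was higher and 5 lower (1 and 5 adjusted over the list alone), with camera adjusted p = 0.153. Of 10 smooth muscle markers, 2 were higher and 6 lower (2 and 6 adjusted over the list alone), with camera adjusted p = 0.0532. Of 12 epithelial and surface ectoderm markers, 0 were higher and 7 lower (0 and 7 adjusted over the list alone), with camera adjusted p = 0.0532. Of 9 pluripotency markers, 2 were higher and 5 lower (2 and 5 adjusted over the list alone), with camera adjusted p = 0.623. Of 6 neural and neural crest markers, 1 was higher and 4 lower (1 and 4 adjusted over the list alone), with camera adjusted p = 0.334. Of 9 mesothelium and epicardium markers, 2 were higher and 4 lower (2 and 4 adjusted over the list alone), with camera adjusted p = 0.962. Of 4 skeletal muscle and somite markers, 2 were higher and 1 lower (3 and 1 adjusted over the list alone), with camera adjusted p = 0.473. Of 4 endoderm markers, 3 were higher and 0 lower (3 and 1 adjusted over the list alone), with camera adjusted p = 0.28. Of 6 blood markers, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), with camera adjusted p = 0.433. Of 4 kidney lineage markers, 2 were higher and 2 lower (2 and 2 adjusted over the list alone), with camera adjusted p = 0.962. The 37 mitochondrially encoded genes had 0 counts in all libraries, for a reason not given in the sources used here, so that list gave no value.

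By edgeR's quasi-likelihood test, 5811 genes were higher and 5658 lower with FGF8+10 at a Benjamini-Hochberg adjusted p under 0.05, and 1645 and 2217 of them by at least 2-fold. Scaled by library totals alone, the median gene moved up by 0.172 (log2) and the split became 8164 higher and 3991 lower, so directions of small changes are relative to the TMM scaling. Replicates differed little (median biological coefficient of variation 3.34% among genes of at least 10 CPM), and the labels call them biological replicates without saying whether they came from separate differentiations, so the p-values measure only the spread between these libraries.

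The second comparison put the same question to the Pdgfra-low cells. KLHL14, a BTB-Kelch protein gene, ETV1 and ETV4, transcription factors downstream of FGF receptors, and ANGPT1, the TEK ligand, rose from group means under 1 CPM. ETV1 went from 0.247 ± 0.025 to 88.7 ± 5.1 CPM (log2 fold change 8.47 ± 0.12, adjusted p = 8.15e-44) and ANGPT1 from 0.923 ± 0.098 to 260 ± 2.4 CPM. FGF10 rose by 3.69 ± 0.093 and MSX1 by 0.95 ± 0.058. FGFR1 rose by 0.79 ± 0.030, and FGFR2 and FGFR4 fell (log2 fold changes -3.53 ± 0.022 and -1.83 ± 0.26), as did FGFR3, from 151 ± 1.9 to 18.8 ± 1.1 CPM (adjusted p = 1.23e-41). The limb genes TBX4 and SHOX2 fell (log2 fold changes -2.60 ± 0.053 and -3.98 ± 0.089), and TBX3 rose by 1.26 ± 0.024.

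The 10 largest rises were KLHL14, GREM1, ETV1, SAMSN1, ANGPT1, PIK3CG, COLEC10, CDH13, ETV4 and GFRA1. CDH13 (T-cadherin) reached 240 ± 0.25 CPM from 1.38 ± 0.3 CPM, and GFRA1, a GDNF co-receptor gene, rose by 7.38 ± 0.15. KLHL14 and GREM1 each had 2 counts in the Mock Pdgfra-low group, so their ratios, 1210 (exact binomial 95% interval over pairs 217 to 47900) and 615 (110 to 24300), are poorly bounded above. The 10 largest falls were CHAT, OSR2, SFRP5, SLC18A3, NPY, ALOX5, ERICH3, SMOC2, SUCNR1 and IGSF10. CHAT, choline acetyltransferase (chromosome 10, 49609095 to 49667942), OSR2, an odd-skipped transcription factor of limb and kidney mesenchyme, and SFRP5, a secreted WNT antagonist, had no read in the FGF8+10 Pdgfra-low libraries against 29.3, 14.1 and 13.7 CPM with Mock, and were at least 545-fold, 262-fold and 255-fold lower. ERICH3 and SUCNR1 had 2 counts each with FGF8+10, for ratios of 405 (72.3 to 16000) and 284 (50.5 to 11200). SLC18A3 lies within the CHAT locus (chromosome 10, 49610310 to 49612720) and fell with it (log2 fold change -11.22 ± 0.16). It had 4 counts in the FGF8+10 Pdgfra-low group, so the SE understates its counting error.

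Of 25 FGF and ERK targets, 17 were higher and 6 lower (17 and 6 adjusted over the list alone), with camera adjusted p = 1.21e-05, and adjusted p = 0.0354 with an estimated correlation. SPRY1 rose by 5.62 ± 0.053 and SPRY4 by 6.61 ± 0.070. Of 25 cell cycle genes, 24 were higher and 0 lower (24 and 0 adjusted over the list alone), with camera adjusted p = 5.29e-20, and adjusted p = 0.013 with an estimated correlation. MKI67, a proliferation marker, rose by 1.54 ± 0.026 and TOP2A by 1.47 ± 0.023. Of 13 BMP targets and antagonists, 10 were higher and 2 lower (10 and 2 adjusted over the list alone), with camera adjusted p = 2.31e-05, and adjusted p = 0.0354 with an estimated correlation. ID3 rose by 2.87 ± 0.057. Of 21 anterior and central HOX genes, 17 were higher and 0 lower (19 and 0 adjusted over the list alone), with camera adjusted p = 6.63e-05, and adjusted p = 0.0354 with an estimated correlation. Of 14 posterior HOX genes, 10 were higher and 3 lower (10 and 3 adjusted over the list alone), with camera adjusted p = 0.0431, but adjusted p = 0.147 with an estimated correlation. HOXC10, a hindlimb HOX gene, rose by 4.78 ± 0.25.

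Endothelial markers rose together. Of 15 endothelial markers, 15 were higher and 0 lower (15 and 0 adjusted over the list alone), with camera adjusted p = 1.6e-08, and adjusted p = 0.0289 with an estimated correlation. PECAM1 went from 0.676 ± 0.043 to 18.5 ± 1.3 CPM and the transcription factor gene ERG rose by 2.94 ± 0.081. Of 18 cholesterol synthesis genes, 13 were higher and 4 lower (13 and 5 adjusted over the list alone), with camera adjusted p = 6.63e-05, and adjusted p = 0.0354 with an estimated correlation. INSIG1 rose by 1.32 ± 0.039. Of 14 p53 targets, 10 were higher and 2 lower (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00157, but adjusted p = 0.119 with an estimated correlation. The cell cycle inhibitor gene CDKN1A rose by 1.04 ± 0.049.

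Other lists fell. Of 20 fibrous connective tissue matrix genes, 6 were higher and 14 lower (6 and 14 adjusted over the list alone), with camera adjusted p = 1.21e-05, and adjusted p = 0.0354 with an estimated correlation. DCN had a log2 fold change of -5.22 ± 0.022 and COL3A1 of -1.83 ± 0.011. Of 14 amino acid stress response genes, 0 were higher and 14 lower (0 and 14 adjusted over the list alone), with camera adjusted p = 1.77e-12, and adjusted p = 0.0203 with an estimated correlation. VLDLR had a log2 fold change of -5.43 ± 0.052. Of 24 limb mesenchyme genes, 5 were higher and 15 lower (5 and 15 adjusted over the list alone), with camera adjusted p = 0.00822, but adjusted p = 0.0886 with an estimated correlation. Of 9 hedgehog targets, 2 were higher and 7 lower (2 and 7 adjusted over the list alone), with camera adjusted p = 0.0159, but adjusted p = 0.147 with an estimated correlation. Of 16 hypoxia response genes, 5 were higher and 8 lower (5 and 8 adjusted over the list alone), with camera adjusted p = 0.0431, but adjusted p = 0.147 with an estimated correlation. Of 10 cardiac muscle markers, 0 were higher and 9 lower (0 and 9 adjusted over the list alone), with camera adjusted p = 0.001, but adjusted p = 0.0634 with an estimated correlation. GAS1, a hedgehog co-receptor gene, fell (log2 fold change -1.96 ± 0.071), and HHIP, a hedgehog-binding antagonist, rose by 4.87 ± 0.21.

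edgeR's quasi-likelihood test called 6300 genes higher and 6256 lower, 2131 and 2664 of them by at least 2-fold. Library totals alone moved the median gene by 0.161 (log2) and the split to 8113 and 4672.

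The FGF8+10 effects of the populations, which share no library, overlapped. A total of 4516 genes were higher in both populations against 1623 expected of independent lists, and 4308 lower in both against 1569 expected. With library totals alone these counts were 6462 and 3055, so the balance of directions depends on the scaling. Opposite calls were made for 462 genes. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.77 and Spearman's rho of 0.71.

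**Figure D3:**
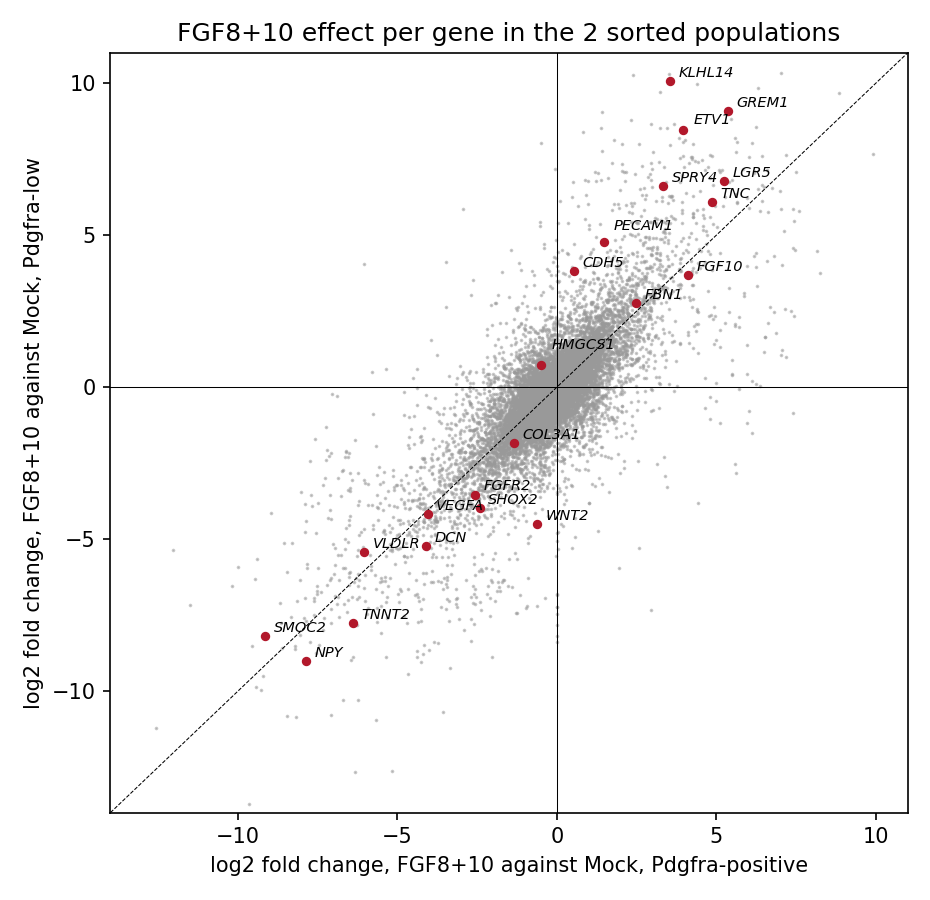
log2 fold change of each tested gene, FGF8+10 against Mock, in Pdgfra-positive (x axis) and Pdgfra-low cells (y axis), with genes on the Y chromosome and XIST left out and the dashed line marking equal effects. Named genes such as FGF10 and FBN1 lie near the line, whereas KLHL14, ETV1 and PECAM1 lie above it and HMGCS1 lies in the quadrant of opposite directions.

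The third comparison asked how the sorted populations differed under FGF8+10. In the Pdgfra-positive cells SHOX2 stood at 14.4 ± 0.1 against 3.03 ± 0.82 CPM. TBX4 and TWIST1, mesenchymal transcription factor genes, were higher by 1.22 ± 0.056 and 1.19 ± 0.044 on the log2 scale, and PDGFRB, the second PDGF receptor gene, by 1.24 ± 0.027. The Pdgfra-low cells held more endothelial transcripts, with CDH5 (VE-cadherin) at 19.8 ± 0.58 against 1.39 ± 0.47 CPM (adjusted p = 1.79e-22), and more of the simple-epithelial keratins KRT8 and KRT18. MSX1 did not pass the threshold between the populations (log2 fold change -0.01 ± 0.055, adjusted p = 0.909).

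The 6 genes highest in Pdgfra-positive cells were ADAMTSL1, SCUBE2, SHOX2, SMOC1, DLG2 and TOX3, with log2 fold changes from 2.00 to 2.30. The 6 highest in Pdgfra-low cells were LRP2, STAB1, GDF15, ESAM, CDH5 and GIMAP4, with log2 fold changes from -5.14 to -3.61. LRP2 (megalin) stood at 13.9 ± 0.27 against 0.391 ± 0.03 CPM. FGF10, FGFR1 and FGFR2 were higher in Pdgfra-positive cells (0.41 ± 0.069, 0.27 ± 0.029 and 0.89 ± 0.022), and FGFR3 was lower (-0.79 ± 0.058).

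Of 20 fibrous connective tissue matrix genes, 16 were higher and 3 lower (16 and 3 adjusted over the list alone), with camera adjusted p = 5.98e-14, and adjusted p = 0.0127 with an estimated correlation. COL6A3 was higher by 1.00 ± 0.017 and COL3A1 by 0.65 ± 0.011. Of 15 endothelial markers, 0 were higher and 14 lower (0 and 14 adjusted over the list alone), with camera adjusted p = 3.82e-10, and adjusted p = 0.0158 with an estimated correlation. ESAM and TIE1 had log2 fold changes of -4.02 ± 0.18 and -3.03 ± 0.16. Beside these endothelial markers, of 25 cell cycle genes, 0 were higher and 24 lower (0 and 24 adjusted over the list alone), with camera adjusted p = 4.34e-21, and adjusted p = 0.00985 with an estimated correlation. CENPF had a log2 fold change of -0.95 ± 0.028. Of 18 cholesterol synthesis genes, 0 were higher and 16 lower (0 and 16 adjusted over the list alone), with camera adjusted p = 2.08e-17, and adjusted p = 0.00985 with an estimated correlation. HMGCS1, of whose exon bases 37.7% overlap an antisense gene, differed by -1.08 ± 0.026. Of 14 p53 targets, 0 were higher and 12 lower (0 and 12 adjusted over the list alone), with camera adjusted p = 7.67e-09, and adjusted p = 0.0346 with an estimated correlation. CDKN1A differed by -2.35 ± 0.053. Of 16 hypoxia response genes, 2 were higher and 11 lower (2 and 11 adjusted over the list alone), with camera adjusted p = 2.03e-05, and adjusted p = 0.0346 with an estimated correlation. Of 14 amino acid stress response genes, 1 was higher and 12 lower (1 and 12 adjusted over the list alone), with camera adjusted p = 2.13e-05, and adjusted p = 0.0346 with an estimated correlation. SLC2A1 differed by -2.02 ± 0.045.

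For 6 lists the call was lost when camera was run with an estimated correlation. The estimate lay above the preset 0.01 only for hedgehog targets (0.026). It was -0.031 for limb mesenchyme, -0.036 for posterior HOX and 0.003 for FGF and ERK targets. For epithelial markers it was -0.056 and for dissociation and heat shock genes -0.034. For the lists below the preset, the larger p does not come from a stronger correlation. Of the 6 lists, 3 stood higher in Pdgfra-positive cells. Of 24 limb mesenchyme genes, 11 were higher and 4 lower (11 and 4 adjusted over the list alone), with camera adjusted p = 0.00867, but adjusted p = 0.0939 with an estimated correlation. Of 14 posterior HOX genes, 7 were higher and 2 lower (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0119, but adjusted p = 0.103 with an estimated correlation. Of 9 hedgehog targets, 6 were higher and 1 lower (6 and 1 adjusted over the list alone), with camera adjusted p = 0.0467, but adjusted p = 0.176 with an estimated correlation. PRRX1, a limb mesenchyme homeobox gene, was higher by 0.92 ± 0.028 and HOXD10 by 0.93 ± 0.050. The other 3 stood lower. Of 25 FGF and ERK targets, 4 were higher and 15 lower (4 and 15 adjusted over the list alone), with camera adjusted p = 0.00443, but adjusted p = 0.091 with an estimated correlation. Of 12 epithelial and surface ectoderm markers, 1 was higher and 7 lower (1 and 7 adjusted over the list alone), with camera adjusted p = 0.011, but adjusted p = 0.103 with an estimated correlation. Of 20 dissociation and heat shock response genes, 5 were higher and 10 lower (5 and 10 adjusted over the list alone), with camera adjusted p = 0.02, but adjusted p = 0.109 with an estimated correlation. DUSP6, an ERK phosphatase gene of whose exon bases 28.6% overlap an antisense gene, was lower (-1.41 ± 0.067). KRT8 (-2.10 ± 0.024) and the chaperone gene HSP90AA1 (-1.05 ± 0.021) were lower too, while the immediate early gene FOS was higher (0.95 ± 0.030). edgeR's quasi-likelihood test called 4430 genes higher and 4905 lower in Pdgfra-positive cells, 705 and 735 by at least 2-fold.

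The fourth comparison asked the same under Mock. Some genes that FGF8+10 raised in both populations were higher in the Pdgfra-positive cells under Mock. ANGPT1 stood at 19.1 ± 0.79 against 0.923 ± 0.098 CPM, ETV1 at 4.92 ± 0.94 against 0.247 ± 0.025 CPM and ALDH1A2 at 7.73 ± 0.89 against 0.437 ± 0.13 CPM (adjusted p = 2.38e-25). FGF10 did not pass the threshold (log2 fold change -0.01 ± 0.13, adjusted p = 0.96). The Pdgfra-low cells held more transcripts of mesothelium, the lining of the body cavities, with UPK3B, a uroplakin gene, lower in Pdgfra-positive cells (log2 fold change -5.25 ± 0.24). PODXL (podocalyxin), a sialomucin gene, stood at 850 ± 17 against 29.0 ± 2.1 CPM. MSX1 was slightly lower in Pdgfra-positive cells (log2 fold change -0.27 ± 0.063).

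The 6 genes highest in Pdgfra-positive cells were ANGPT1, COLEC10, ALDH1A2, CDH13, TNFRSF1B and NPR1, and the 6 highest in Pdgfra-low cells were TMEM151A, UPK3B, PKHD1L1, PODXL, LRP2 and TMEM255A. The first ranged from 3.09 to 4.37 in log2 fold change and the second from -5.56 to -4.62.

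Of 25 FGF and ERK targets, 11 were higher and 4 lower (13 and 5 adjusted over the list alone), with camera adjusted p = 0.00463, but adjusted p = 0.0896 with an estimated correlation. SPRY1, SPRY4, ETV1 and EGR1 were higher by 2.27 ± 0.070, 2.49 ± 0.10, 4.30 ± 0.20 and 1.54 ± 0.054. Of 14 posterior HOX genes, 8 were higher and 0 lower (10 and 0 adjusted over the list alone), with camera adjusted p = 0.000134, and adjusted p = 0.0389 with an estimated correlation. Of 20 fibrous connective tissue matrix genes, 12 were higher and 4 lower (12 and 4 adjusted over the list alone), with camera adjusted p = 3.91e-10, and adjusted p = 0.0266 with an estimated correlation. Of 18 cholesterol synthesis genes, 10 were higher and 0 lower (11 and 0 adjusted over the list alone), with camera adjusted p = 2.31e-05, and adjusted p = 0.0311 with an estimated correlation. HOXD9 was higher by 1.06 ± 0.082 and FBN1 by 0.70 ± 0.017. Of 11 retinoic acid pathway genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone), with camera adjusted p = 0.0317, but adjusted p = 0.15 with an estimated correlation. The median of the retinoic acid list was 0.04 and its mean -0.17, while the test pointed upwards.

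Mesothelial and epithelial markers were lower in Pdgfra-positive cells. Of 9 mesothelium and epicardium markers, 1 was higher and 6 lower (1 and 6 adjusted over the list alone), with camera adjusted p = 1.53e-05, and adjusted p = 0.0311 with an estimated correlation. Of 12 epithelial and surface ectoderm markers, 1 was higher and 5 lower (1 and 5 adjusted over the list alone), with camera adjusted p = 1.53e-05, and adjusted p = 0.0311 with an estimated correlation. BNC1, a mesothelial transcription factor gene, differed by -2.23 ± 0.065 and KRT8 by -1.36 ± 0.024. Beside these cell type markers, of 14 amino acid stress response genes, 0 were higher and 14 lower (0 and 14 adjusted over the list alone), with camera adjusted p = 9.31e-16, and adjusted p = 0.0247 with an estimated correlation. Of 14 p53 targets, 0 were higher and 13 lower (0 and 13 adjusted over the list alone), with camera adjusted p = 6.36e-09, and adjusted p = 0.0266 with an estimated correlation. Of 16 hypoxia response genes, 1 was higher and 9 lower (1 and 9 adjusted over the list alone), with camera adjusted p = 1.06e-07, and adjusted p = 0.0266 with an estimated correlation. Of 25 cell cycle genes, 1 was higher and 17 lower (1 and 18 adjusted over the list alone), with camera adjusted p = 1.55e-06, and adjusted p = 0.0266 with an estimated correlation. Of 14 WNT targets, 1 was higher and 5 lower (1 and 7 adjusted over the list alone), with camera adjusted p = 0.00134, but adjusted p = 0.198 with an estimated correlation. Of 6 neural and neural crest markers, 1 was higher and 3 lower (1 and 3 adjusted over the list alone), with camera adjusted p = 0.00551, but adjusted p = 0.0931 with an estimated correlation. DKK1, a WNT antagonist and target, was lower (-2.30 ± 0.059), as was STMN2, a neuronal microtubule regulator gene (-3.71 ± 0.065).

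edgeR's quasi-likelihood test called 2797 genes higher and 3027 lower in Pdgfra-positive cells under Mock, 368 and 507 by at least 2-fold. The differences between populations under FGF8+10 and under Mock, which share no library, had 1691 genes higher in both (549 expected of independent lists), 1953 lower in both (658 expected) and 601 opposite, with Pearson's r of 0.23 and Spearman's rho of 0.32 across genes.

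Cells were sorted after the treatment, so a gate may hold different cells under FGF8+10 and under Mock. Within that limit, the fifth comparison tested whether the FGF8+10 effect itself differed between populations. It was smaller in Pdgfra-positive cells for the FGF-responsive genes ETV1 (difference of log2 fold changes -4.50 ± 0.21, adjusted p = 2.51e-22), SPRY4 (-3.28 ± 0.11) and SPRY1 (-2.05 ± 0.079). The Mock levels of these were higher in Pdgfra-positive cells. With FGF8+10 ETV1 reached 76.7 ± 2.5 CPM in Pdgfra-positive and 88.7 ± 5.1 CPM in Pdgfra-low cells, from 4.92 ± 0.94 and 0.247 ± 0.025 CPM with Mock. SPRY1 reached 202 ± 0.91 and 172 ± 2.3 CPM from 16.9 ± 0.62 and 3.5 ± 0.19 CPM, and SPRY4 90.6 ± 5.0 and 157 ± 2.4 CPM from 8.99 ± 0.03 and 1.6 ± 0.0078 CPM. For ETV1 and SPRY1 the populations thus differed mainly with Mock. Endothelial genes rose more in Pdgfra-low cells, with ESAM at -4.34 ± 0.32 and ERG at -2.42 ± 0.11. The matrix genes DCN (1.13 ± 0.028) and POSTN (1.11 ± 0.031) fell less in Pdgfra-positive cells, and so did the limb genes TBX4 (1.19 ± 0.072) and SHOX2 (1.57 ± 0.12). The rise of PDGFRA did not pass the threshold for a difference (0.08 ± 0.034, adjusted p = 0.0918), but passed under 4 alternatives (adjusted p from 0.00953 to 0.278 over all).

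Cholesterol synthesis genes gave the smallest adjusted p of the lists. Higher and lower effects are those of Pdgfra-positive relative to Pdgfra-low cells. Of 18 cholesterol synthesis genes, 0 had a higher and 17 a lower effect (0 and 17 adjusted over the list alone), with camera adjusted p = 8.3e-32, and adjusted p = 0.00582 with an estimated correlation. HMGCS1 differed by -1.22 ± 0.037. Of 25 cell cycle genes, 0 had a higher and 20 a lower effect (0 and 21 adjusted over the list alone), with camera adjusted p = 7.42e-14, and adjusted p = 0.0138 with an estimated correlation. Of 20 fibrous connective tissue matrix genes, 14 had a higher and 5 a lower effect (14 and 5 adjusted over the list alone), with camera adjusted p = 1.03e-11, and adjusted p = 0.0149 with an estimated correlation. Of 25 FGF and ERK targets, 2 had a higher and 15 a lower effect (2 and 16 adjusted over the list alone), with camera adjusted p = 1.2e-07, and adjusted p = 0.0203 with an estimated correlation. Of 15 endothelial markers, 0 had a higher and 12 a lower effect (0 and 13 adjusted over the list alone), with camera adjusted p = 4.69e-11, and adjusted p = 0.0149 with an estimated correlation. Of 20 dissociation and heat shock response genes, 0 had a higher and 12 a lower effect (0 and 12 adjusted over the list alone), with camera adjusted p = 6.9e-08, and adjusted p = 0.0197 with an estimated correlation. Of 18 lateral plate mesoderm genes, 12 had a higher and 2 a lower effect (12 and 2 adjusted over the list alone), with camera adjusted p = 2.96e-06, and adjusted p = 0.0242 with an estimated correlation.

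Another 6 lists passed with the preset correlation of camera but not with an estimated one. The estimates for WNT (0.135), p53 (0.053) and hedgehog targets (0.028) lay above the preset 0.01. Those for limb mesenchyme (-0.038), mesothelium and epicardium markers (-0.101) and pluripotency markers (-0.034) lay below it. For the lists below it, the larger p does not come from a stronger correlation. Of 24 limb mesenchyme genes, 11 had a higher and 2 a lower effect (12 and 2 adjusted over the list alone), with camera adjusted p = 0.000809, but adjusted p = 0.057 with an estimated correlation. Of 9 hedgehog targets, 7 had a higher and 1 a lower effect (7 and 1 adjusted over the list alone), with camera adjusted p = 0.000249, but adjusted p = 0.0586 with an estimated correlation. Of 9 mesothelium and epicardium markers, 4 had a higher and 0 a lower effect (5 and 0 adjusted over the list alone), with camera adjusted p = 0.000661, but adjusted p = 0.0585 with an estimated correlation. Of 14 WNT targets, 4 had a higher and 1 a lower effect (4 and 1 adjusted over the list alone), with camera adjusted p = 0.0253, but adjusted p = 0.347 with an estimated correlation. Of 14 p53 targets, 1 had a higher and 8 a lower effect (1 and 8 adjusted over the list alone), with camera adjusted p = 0.0116, but adjusted p = 0.179 with an estimated correlation. Of 9 pluripotency markers, 0 had a higher and 5 a lower effect (0 and 5 adjusted over the list alone), with camera adjusted p = 0.0253, but adjusted p = 0.153 with an estimated correlation.

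edgeR's quasi-likelihood test called 2697 genes with a higher and 3165 with a lower effect in Pdgfra-positive cells, 468 and 534 of them with a difference of at least 1 on the log2 scale.

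**Figure D4:**
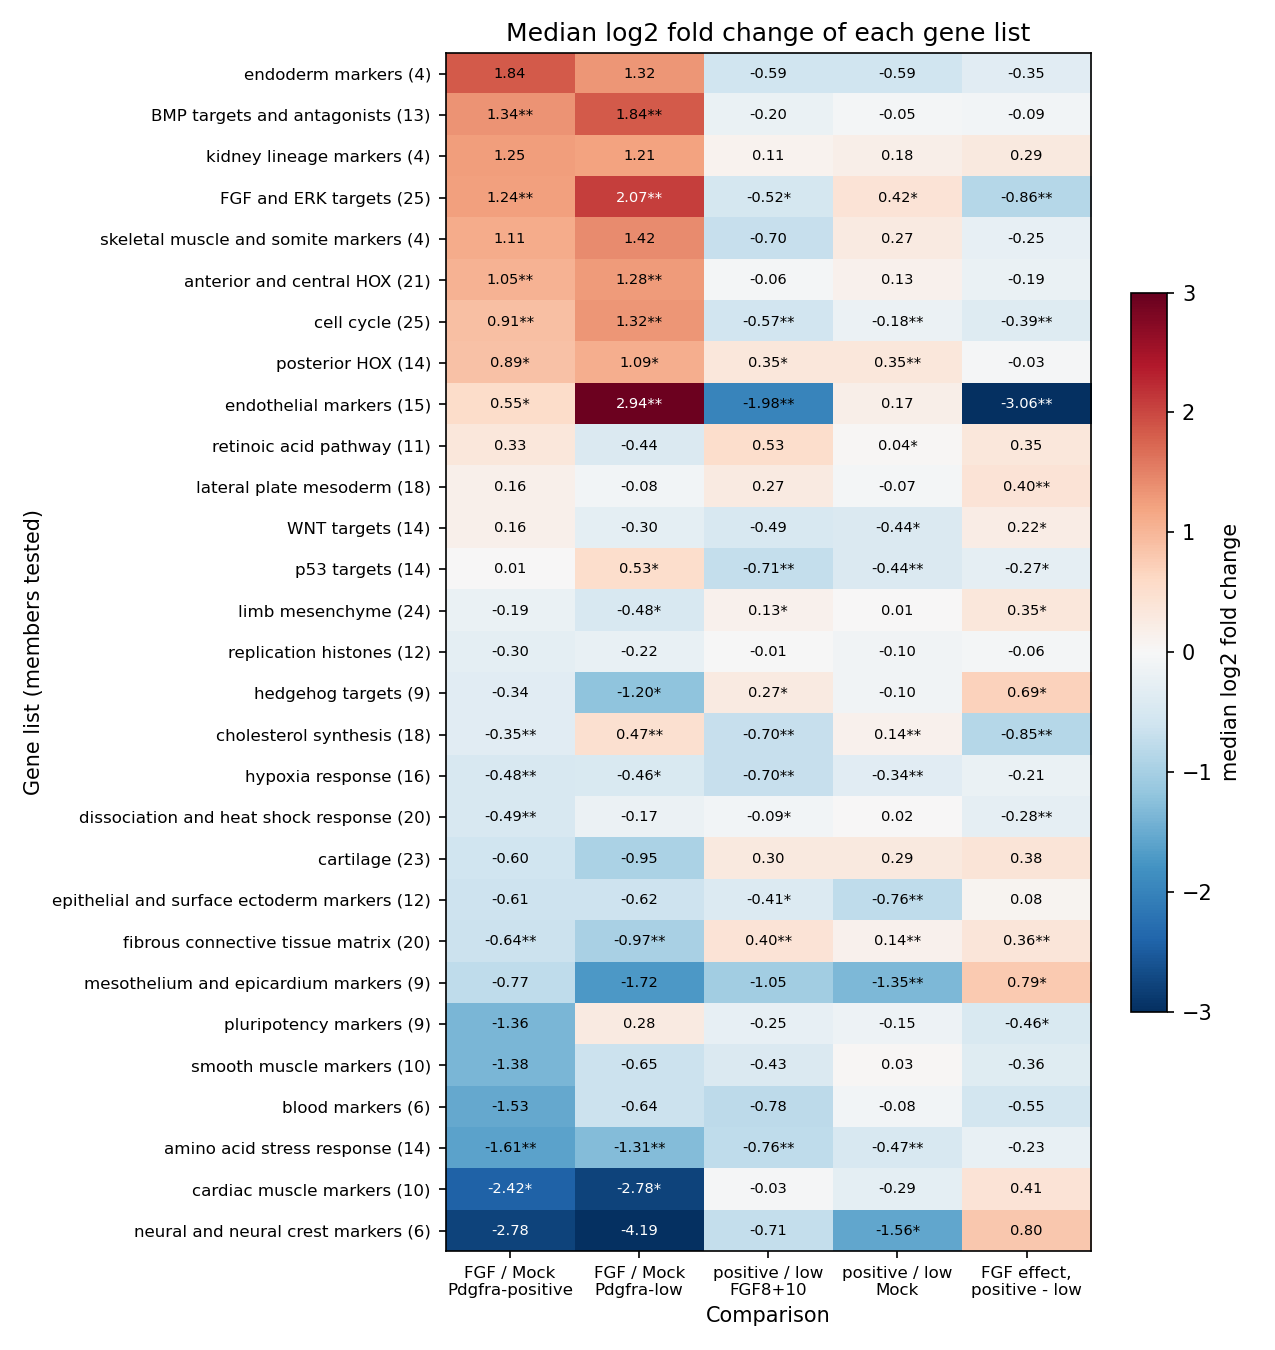
Median log2 fold change (colour and number) of each gene list with at least 3 tested members (rows, number tested in parentheses) in the 5 comparisons (columns), ordered by the first column. One asterisk marks a camera adjusted p under 0.05, and a second that it also held with an estimated correlation. Some medians rest on members without reads in a group. With those at a floor of 6 counts, cardiac muscle in Pdgfra-low cells goes from -2.78 to -1.79. FGF and ERK targets between populations under FGF8+10 go from -0.52 to -0.21, and the cartilage difference of effects, not called, from 0.38 to -0.14. Other medians that were not called move too. The cardiac muscle difference of effects goes from 0.41 to -0.08, and pluripotency markers with FGF8+10 in Pdgfra-positive cells from -1.36 to -0.72. Between populations under FGF8+10, cardiac muscle goes from -0.03 to -0.46 and cartilage from 0.3 to 0.05. FGF and ERK targets and cell cycle genes are positive in the first 2 columns, and the median of cholesterol synthesis genes is -0.35 in the first and 0.47 in the second.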

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

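The difference between the FGF8+10 effects of the populations was planned before the data were examined, while every test of an explanation given here was chosen after the results were seen. The FGF8+10 effect was higher in Pdgfra-positive than in Pdgfra-low cells for 2697 genes and lower for 3165 (edgeR's quasi-likelihood test of the difference, Benjamini-Hochberg adjusted). The genes with the largest positive differences of log2 fold changes were SFRP5 (7.45), OSR2 (6.35), ERICH3 (4.32), TMEM151A (4.32), CA12 (4.15) and WNT2 (3.89), all of which fell in both populations and fell further in Pdgfra-low cells. Those of SFRP5, OSR2 and ERICH3 rest on 0 to 2 reads in the FGF8+10 Pdgfra-low group and depend on the prior count. Without replicate 2 of the FGF8+10 Pdgfra-positive group, the difference of ERICH3 was -1.24. The largest negative differences were those of RPSAP44 (-6.68), KLHL14 (-6.50), PIK3CG (-6.34), GIMAP4 (-6.02), MRC1 (-5.37) and MMRN1 (-5.31). RPSAP44, a pseudogene, had no read in the FGF8+10 Pdgfra-positive group and KLHL14 had 2 in the Mock Pdgfra-low group, so those values also depend on the prior count.

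Among gene lists, the median difference of the effects was -3.06 for endothelial markers, -0.86 for FGF and ERK targets (-0.80 with unread genes at their bound), -0.85 for cholesterol synthesis, -0.46 for pluripotency markers (-0.43 at the bound), -0.39 for cell cycle, -0.28 for dissociation and heat shock response and -0.27 for p53 targets. It was 0.22 for WNT targets, 0.35 for limb mesenchyme, 0.36 for fibrous connective tissue matrix, 0.40 for lateral plate mesoderm, 0.69 for hedgehog targets and 0.79 for mesothelium and epicardium markers. Of these 13 calls, 6 were lost with an estimated correlation, namely pluripotency markers (adjusted p = 0.153), p53 targets (adjusted p = 0.179), WNT targets (adjusted p = 0.347), limb mesenchyme (adjusted p = 0.057), hedgehog targets (adjusted p = 0.0586) and mesothelium and epicardium markers (adjusted p = 0.0585).

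In Mock Pdgfra-positive cells, genes that FGF8+10 raised stood above their level in Mock Pdgfra-low cells, among them ANGPT1, ETV1, SPRY1 and ALDH1A2. Reads or RNA of the FGF8+10 libraries mixed into the Mock Pdgfra-positive libraries would add 1 common share of each gene's FGF8+10 level. The test took 22 genes with at least 20 CPM in FGF8+10 Pdgfra-positive cells and less than 2% of that in Mock Pdgfra-low cells. Their share of the FGF8+10 Pdgfra-positive level ran from 1.64% to 10.5% (median 5.59%). For every weighting of the 2 FGF8+10 populations the highest share was at least 6.39 times the lowest, which argues against mixing as the whole cause. TM4SF1 allows a share of at most 2.96%, which leaves over 50% of the level of 13 of the 22 genes unaccounted for. FGF signalling in these cells without FGF8+10 may be the source and stays open, since the Mock medium is not described. The list of FGF and ERK targets passed camera with the preset correlation but had an adjusted p = 0.0896 with an estimated correlation. That estimate was 0.006, below the preset 0.01, so the larger p does not come from a stronger correlation.

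Endothelial markers stood higher in Pdgfra-low than in Pdgfra-positive cells under FGF8+10. A lower share of the main cell type in the Pdgfra-low gate would raise the markers of every other type alike. Of 42 markers from 10 other cell type lists, 9 were called higher in Pdgfra-positive cells, 22 lower and 11 did not pass, so not all moved alike. Over all 22554 genes 4430 were called higher and 4905 lower, so 9 of 42 is near the share over all genes. The 22 lower exceed that share and go with the explanation, so these counts cannot decide. Of 11 endothelial markers under 5 CPM in Pdgfra-positive cells, 10 (90.9%) were at least 2-fold higher in Pdgfra-low cells, but markers picked for a low level in 1 of the compared groups restate the pattern, so this decides nothing. The most abundant members, TEK, FLT1 and EGFL7, stood at 490.82, 113.17 and 81.10 CPM in Pdgfra-positive and 482.87, 189.09 and 133.09 CPM in Pdgfra-low cells. A lower share of the main cell type in the Pdgfra-low gate stays open. So do endothelial cells within that gate and endothelial gene expression in cells of the main type, since pooled RNA holds no single-cell values.

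Cholesterol synthesis genes were lower with FGF8+10 in Pdgfra-positive cells (median -0.35) and higher in Pdgfra-low cells (median 0.47). Library scaling is argued against, since with library totals alone the medians were -0.18 and 0.63 and kept their signs. A single library is argued against too, since the median difference nearest 0 without any 1 library was -0.83. The difference between the FGF8+10 effects passed its planned test (camera adjusted p = 8.3e-32, and adjusted p = 0.00582 with an estimated correlation), while what in the sorted populations underlies it was not tested and stays open.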

How the results depend on the processing

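The alternatives were planned before the data were examined, except halved counts and the test against a 2-fold change (glmTreat), which were chosen after seeing the data. Of 322 counts under alternatives 290 stayed within 1.5 times the reported count, and 0 of 65 called list medians changed sign with median-ratio factors or library totals. With at least 5 CPM in 2 libraries, the numbers of genes at least 2-fold higher and lower were 801 and 945 for FGF8+10 in Pdgfra-positive cells, 1060 and 1135 in Pdgfra-low cells, 284 and 296 between populations under FGF8+10, 154 and 216 under Mock, and 234 and 273 for the difference of effects, since fewer genes were tested. glmTreat, which asks for more than an estimate over 2-fold, gave in the same order 987 and 1365, 1700 lower in Pdgfra-low cells, 133 and 258, 84 and 204, and 102 and 166. Without 1 library, counts changed by at most 1.36 times.

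With an estimated correlation, 2 lists were lower with FGF8+10 in Pdgfra-low cells, 1 higher between populations under FGF8+10, 3 higher under Mock and 2 higher for the difference. fry, which does not compare a list with other genes, called 11 lists higher and 16 lower in Pdgfra-positive cells, 13 and 13 in Pdgfra-low cells, 8 and 17 between populations under FGF8+10, 9 and 14 under Mock, and 13 lower for the difference.

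The replicate numbers were not treated as pairs, since deviations of same-numbered replicates correlated at -0.006 to 0.033. With the replicate number as a block, 5767 genes were higher and 5599 lower in Pdgfra-positive cells, all counts were 0.940 to 0.999 of those reported, and 1 list call was lost, hypoxia response in Pdgfra-low cells (adjusted p = 0.056). A fit of the compared groups alone is not possible for the difference of effects.

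Of 3158 values of 238 results for named genes under alternatives, 3 lost and 4 gained the threshold and 1 reversed. The difference of ERICH3 ranged from -1.24 to 7.55 when 1 library was left out, and it lost the threshold with limma-voom and DESeq2 (adjusted p = 0.203 and 0.156, against 1.63e-06 to 0.703 over all alternatives). All 14 of its reads in the FGF8+10 Pdgfra-positive group lay in replicate 2. HOXB13 in Pdgfra-positive cells lost it with library totals (log2 fold change -0.06, adjusted p = 0.323, against 1.86e-06 to 0.323 over all). The difference of PDGFRA gained it with library totals, without a filter, with at least 5 CPM in 2 libraries and without replicate 2 of the FGF8+10 Pdgfra-low group, and ranged from 0.06 to 0.13. The cause was not tested for HOXB13 and PDGFRA. A group with 1 library left is assumed to vary like the others. Genes with few reads are limited by depth, since 6 counts, or 3 pairs, are 0.0932 to 0.126 CPM in 1 library.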

Other observations

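The tests of gene families given here are from 50, of 10 families defined by their symbols in 5 comparisons, that were chosen after the results were seen, as were the single genes named, and p-values were adjusted over the 50. That adjustment does not cover the choice of the families, so the family p-values are descriptive. The tests of cell type markers were planned and adjusted over the 29 lists of a comparison. In the HOXB cluster 8 of 9 tested genes were lower in Pdgfra-positive cells under FGF8+10 and 1 higher (median log2 fold change -0.67, camera adjusted p = 0.000446, but adjusted p = 0.0502 with an estimated correlation), with HOXB2 at -1.12 ± 0.10. In the HOXD cluster 7 of 8 were higher and 0 lower (median 0.84, adjusted p = 8.52e-05, and adjusted p = 0.0388 with an estimated correlation), with HOXD9 at 1.00 ± 0.068. The HOXA cluster (1 of 11 higher, 0 lower, adjusted p = 0.164) and the HOXC cluster (2 of 7 higher, 2 lower, adjusted p = 0.693) were not called. Under Mock, HOXD genes were again higher in Pdgfra-positive cells, 4 of 8 with 0 lower (median 0.56, adjusted p = 0.002, but adjusted p = 0.0502 with an estimated correlation), and so were 4 of 11 HOXA genes with 0 lower (median 0.64, adjusted p = 0.0408, but adjusted p = 0.125 with an estimated correlation). The HOXB cluster (2 of 9 higher, 3 lower, adjusted p = 0.335) and the HOXC cluster (1 of 7 higher, 1 lower, adjusted p = 0.413) were not called under Mock. FGF8+10 itself raised 8 of 9 HOXB genes in Pdgfra-positive (adjusted p = 0.000195, and adjusted p = 0.0484 with an estimated correlation) and in Pdgfra-low cells (adjusted p = 3.72e-05, and adjusted p = 0.0388 with an estimated correlation). It raised 8 of 8 HOXD genes in Pdgfra-positive (adjusted p = 9.55e-05, and adjusted p = 0.0388 with an estimated correlation) and in Pdgfra-low cells (adjusted p = 0.0045, but adjusted p = 0.0616 with an estimated correlation). Of 15 endothelial markers, 14 were lower in Pdgfra-positive cells under FGF8+10 (adjusted p = 3.82e-10, and adjusted p = 0.0158 with an estimated correlation). FGF8+10 raised 15 of 15 in Pdgfra-low cells (adjusted p = 1.6e-08, and adjusted p = 0.0289 with an estimated correlation) and raised 9 and lowered 2 in Pdgfra-positive cells (adjusted p = 0.0178, but adjusted p = 0.114 with an estimated correlation). The difference of the FGF8+10 effects was not called for HOXB (adjusted p = 0.0979) or HOXD genes (adjusted p = 0.469). The medians of HOXB and HOXD had the same sign with median-ratio factors and with library totals. Genes of a cluster are neighbours and may not be independent, and reads over exons they share were dropped.

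Of 36 genes of the proteasome, the main protease of the cytosol, 31 were lower and 2 higher in Pdgfra-positive cells under FGF8+10 (median -0.41, adjusted p = 2.84e-14, and adjusted p = 0.0342 with an estimated correlation), and 24 lower and 1 higher under Mock (median -0.16, adjusted p = 1.3e-07, and adjusted p = 0.0388 with an estimated correlation). PSMD1 differed by -0.75 ± 0.030 under FGF8+10. All 8 subunit genes of the CCT chaperonin, which folds actin and tubulin, were lower in Pdgfra-positive cells under FGF8+10 (median -0.53, adjusted p = 1.42e-10, and adjusted p = 0.0388 with an estimated correlation), with CCT5 at -1.03 ± 0.028. In the same comparison 14 of 15 endothelial markers were lower (median -1.98, adjusted p = 3.82e-10, and adjusted p = 0.0158 with an estimated correlation), as were 7 of 12 epithelial markers (adjusted p = 0.011, but adjusted p = 0.103 with an estimated correlation). Under Mock, 7 of 8 CCT genes were lower (median -0.22, adjusted p = 5.77e-08, but adjusted p = 0.0502 with an estimated correlation). FGF8+10 raised 28 of 36 proteasome genes in Pdgfra-low cells (adjusted p = 5.94e-08, and adjusted p = 0.0388 with an estimated correlation) and 15 of 36 in Pdgfra-positive cells (adjusted p = 0.0629). The test of that difference found 25 of 36 with a smaller effect in Pdgfra-positive cells and 0 with a larger one (adjusted p = 8.47e-10, and adjusted p = 0.0388 with an estimated correlation). Of 15 endothelial markers, which FGF8+10 raised in Pdgfra-low cells, 12 had a lower effect in Pdgfra-positive cells (adjusted p = 4.69e-11, and adjusted p = 0.0149 with an estimated correlation). Of 10 annexin genes, which encode membrane-binding proteins, 8 were lower in Pdgfra-positive cells under Mock and 0 higher (median -0.39, adjusted p = 2.64e-09, and adjusted p = 0.0342 with an estimated correlation), with ANXA2 at -1.46 ± 0.027. Under Mock, 6 of 9 mesothelium and epicardium markers and 5 of 12 epithelial markers were lower too (both adjusted p = 1.53e-05, and adjusted p = 0.0311 with an estimated correlation). Under FGF8+10, 7 annexin genes were lower and 1 higher (median -0.52, adjusted p = 0.000233, but adjusted p = 0.0502 with an estimated correlation).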
